A study of Rattus norvegicus with 11 samples.

How the data were processed

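RNA was sequenced from cardiac tissue of Sprague Dawley rats. Per the labels' protocols, total RNA was isolated with a Qiagen kit and libraries followed standard Illumina methods. The submitters' processing notes name CASAVA 1.8 and TopHat2 2.0.6. The counting tool, its strand setting, the genome build and the annotation release are not given in the sources used here, so genes that overlap or share reads with a near-identical copy are uncertain.

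The authors deposited 1 table with raw counts per gene, which per the file headers holds a count column for each of the 11 libraries. The same deposited table holds FPKM values, counts scaled by gene model length and by the total of the library, for each library. The counts were whole numbers with totals that differed between libraries. The table has 32883 Ensembl rat gene IDs, of which 12047 were at 0 in every library. The ratio of count to FPKM gave a gene model length for 20836 genes. These lengths differed between libraries by at most 4.87e-05 in relative terms, over genes with 20 or more counts in both libraries. Of the lengths of tested genes, 41.7% were a multiple of 3, so they are not all coding lengths, and the median was 2414 bases. FPKM was used for nothing else.

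Each library was matched to its column by the number in its label. Groups were taken from the labels. No libraries held identical values, and each pair within a group differed by more than counting noise, with chi-square per degree of freedom from 30.6 to 382. Groups share no library number, so no pairing was used.

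The annotation table used here pairs none of the Ensembl IDs with a symbol: 0 IDs matched. The rule fixed beforehand for named genes asked for called genes with a symbol, for members of gene lists and for a fixed set of heart, matrix and retinoid genes in every comparison. It could not be applied, and the gene lists, including those of retinoid metabolism and of cell type markers, were not analysed here. The rule's last part, the genes with the smallest unadjusted p where fewer than 10 were called, was kept for up to 2 IDs in each direction per comparison. Genes that DESeq2 alone called, ENSRNOG00000013589, ENSRNOG00000019118, ENSRNOG00000006889 and ENSRNOG00000022778, were chosen after their values were seen.

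The main test was edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM factors and genes kept by filterByExpr, which left 14979. A quasi-likelihood model with robust estimation was fitted to all 11 libraries with the 4 group means, and p-values were adjusted with the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. There were 6 comparisons of 2 groups and 1 joint test of the 3 isoproterenol-treated groups. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives, and sva 3.50.0 gave a surrogate variable. CPM (counts scaled to 1e6 in TMM-scaled library size) gave the levels of single genes, and distances and principal components used log2 CPM with a prior count of 2. Intervals and floors on counts cover counting error only. The confidence level was 95%.

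The correlation that asks about reversal was set beside 50 simulations of unchanged groups and 100 random regroupings of the libraries. The test of group separation used distances from Spearman correlations and all assignments of libraries to groups. The edgeR step was tested on simulated data with 14979 genes, 200 of them changed, in 5 draws per comparison. At a coefficient of variation of 0.1 it called 91.6% of genes changed 2-fold for isoproterenol against control and 96.4% for canagliflozin against isoproterenol, with 0 calls in the wrong direction.

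The test, the threshold, the comparisons and most alternatives were fixed before the data were examined. The alternatives were other normalisations, filters, thresholds and tests, thinning to the smallest library, a surrogate variable, fits of only the groups compared and leaving out each library. Those chosen after the data had been seen were sample quality weights, library number below 100 as a covariate, removal of libraries 57, 78, 95 and 98, DESeq2 without control library 95 and removal of the 10 most abundant genes. Group separation, the length trend with its use as an offset, and the use of counts at an unadjusted p for other splits of the libraries were also chosen after the data had been seen. Figures were drawn with matplotlib 3.10.9.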

Results

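Gene expression was measured by RNA sequencing of cardiac tissue from Sprague Dawley rats in 11 libraries. The control group had 2 libraries, numbered 115 and 95 in their labels. The isoproterenol group had 3 libraries (79, 98 and 119) from rats given isoproterenol, a beta-adrenergic agonist used to produce heart failure in rodents, at 5 mg/kg per day for 10 days. The canagliflozin group had 3 libraries (78, 133 and 143) from rats given the same isoproterenol course and canagliflozin, an inhibitor of renal glucose reabsorption, at 3 mg/kg per day for 4 weeks. The exercise group had 3 libraries (103, 113 and 57) from rats given isoproterenol and exercised for 60 min per day for 4 weeks. The title and the design text of the series speak of canagliflozin combined with aerobic exercise. The labels of the exercise libraries name no canagliflozin, so the group is called here by its label. Whether these rats also received canagliflozin cannot be told, so comparisons with this group may not isolate exercise. Nothing in the labels beyond the library numbers says that the libraries came from separate animals, so p-values measure the spread between these libraries only.

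Total counts per library ranged from 14742164 to 25034831. The mean total was 14913950 ± 242942 (SD, n = 2) in the control group, 19579564 ± 1405361 (n = 3) in the isoproterenol group, 20542910 ± 4009098 (n = 3) in the canagliflozin group and 19651654 ± 3668986 (n = 3) in the exercise group. Of 32883 gene IDs, 14979 had enough counts to be tested. The files do not pair these IDs with gene names, so genes are given by ID and no pathway or cell type is named.

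Control library 95 differed from the other 10 libraries. It had counts in 14692 genes, against 16916 to 17703 in the others. Its 10 most abundant genes took 42.5% of its counts (95% Wilson interval 42.5 to 42.6%), against 22.6 to 34.3% in the others. Its TMM normalisation factor was 0.568, against 0.910 to 1.23. Its mean distance to the other libraries, as the root mean square difference in log2 CPM (library-scaled read counts), was 1.95, against 0.851 to 1.17. The other control library, 115, had a mean distance of 0.890.

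**Figure D1:**
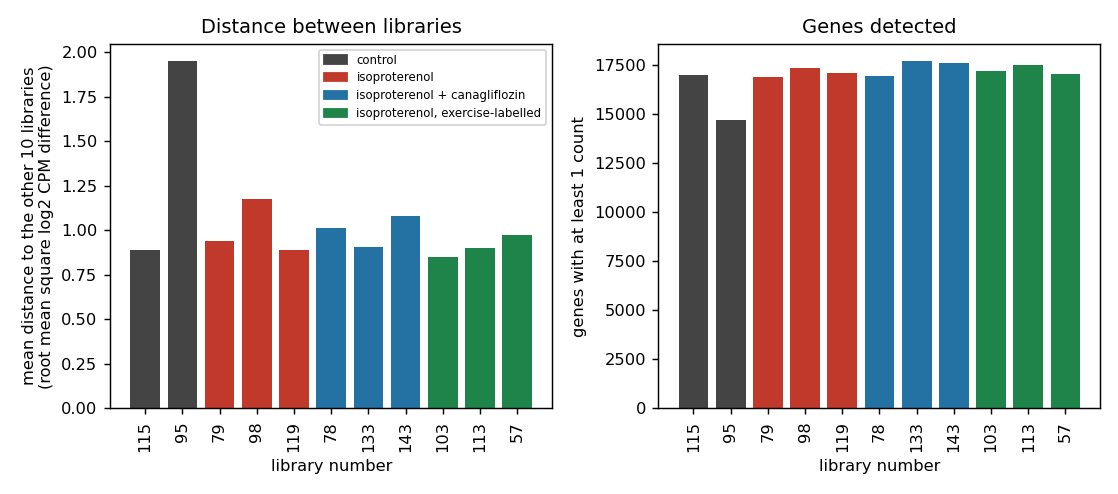
Left, mean distance of each library to the other 10, as root mean square difference in log2 CPM. Right, number of genes with at least 1 count. Each bar is 1 library, coloured by group and marked by its library number. Control library 95 has the highest distance, 1.95, and the fewest genes, 14692.

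Libraries of the same group were about as similar as libraries of different groups. The mean Spearman correlation of gene counts was 0.936 over 10 pairs from the same group and 0.931 over 45 pairs from different groups, and both medians were 0.947. For a test of group separation, the distance was taken from these Spearman correlations and not from the root mean square difference in log2 CPM. The 4 groups accounted for 32.9% of the squared distance between libraries. A one-sided exact permutation test over 92400 assignments of libraries to groups gave p = 0.451. Among the 9 isoproterenol-treated libraries, the 3 groups accounted for 14.2% of the squared distance (exact permutation p = 0.75 over 1680 assignments). Without control library 95 the 4 groups accounted for 18.2% (exact permutation p = 0.832 over 16800 assignments). These 3 tests were chosen after the distances had been seen.

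**Figure D2:**
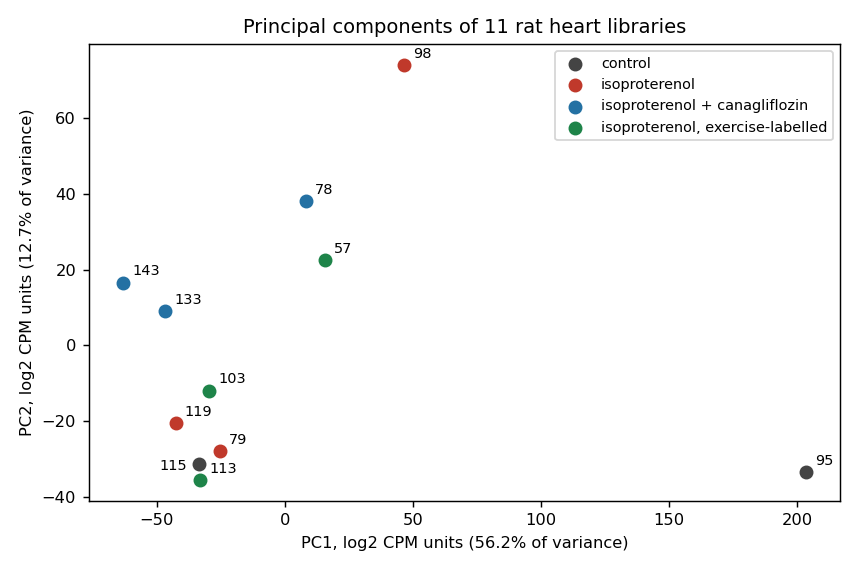
First and second principal components of log2 CPM over the 14979 tested genes, with 56.2% and 12.7% of the variance. Each point is 1 library, coloured by group and marked by its library number. Control library 95 lies apart from the rest on the first component, and the isoproterenol, canagliflozin and exercise libraries overlap.

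Isoproterenol was compared with control to find the genes that the heart failure model changed. The edgeR quasi-likelihood test called 0 of 14979 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.84. At an unadjusted p under 0.05 there were 780 genes, 213 higher and 567 lower with isoproterenol, where evenly spread p-values give 749. limma-voom called 0 genes. DESeq2 called 2 genes, both higher with isoproterenol: ENSRNOG00000013589, with a log2 fold change of 0.92, and ENSRNOG00000003869, with 0.96, both at a DESeq2 adjusted p of 0.0414. Normalised counts of ENSRNOG00000003869 were 139.6 ± 12.0 CPM (SD, n = 3) with isoproterenol and 70.2 ± 8.17 CPM (n = 2) in control. Without control library 95, DESeq2 called 1 gene, which was neither of these. It was ENSRNOG00000022778, with a log2 fold change of 2.37 and a DESeq2 adjusted p of 1.61e-06. With control library 115 as the only control, DESeq2 called this gene in all 3 comparisons with control, which share that library. With both controls its edgeR log2 fold change for isoproterenol against control was 0.61 (SE 0.549). With the length trend of each library as an offset DESeq2 called 0 of the genes tested by edgeR, but its adjustment then ran over a different set of genes. The DESeq2 log2 fold change went from 0.91 (SE 0.210) to 0.65 (SE 0.283) for ENSRNOG00000013589, with an adjusted p of 0.6, and from 0.95 (SE 0.214) to 0.89 (SE 0.215) for ENSRNOG00000003869, with an adjusted p of 0.166. Groups did not overlap in 13.4% of genes, where chance gives 20%.

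The lowest p-values of this comparison came from genes with few counts in control or with a high value in 1 control library. ENSRNOG00000033202 had 0 counts in both control libraries, which allows up to 3 counts per library, and 10, 15 and 15 counts in the isoproterenol libraries. ENSRNOG00000003136 was at 0.592 ± 0.125 CPM (n = 3) with isoproterenol and at 0.707 and 30.9 CPM in the control libraries. With control library 115 left out, which leaves library 95 as the only control and assumes that it varies like the other groups, edgeR called 2688 genes. With control library 95 left out, it called 0, and 148 genes had an unadjusted p under 0.05.

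The canagliflozin group was compared with isoproterenol alone to find what the drug changed. edgeR called 0 genes, with a smallest adjusted p of 0.999. There were 495 genes at an unadjusted p under 0.05, 362 higher and 133 lower with canagliflozin, where evenly spread p-values give 749. This count was 572 in a fit of only the groups compared, 1129 with a surrogate variable and 220 without canagliflozin library 133. Its side of 749 therefore depends on the fit, and other splits of the same libraries gave 106 to 1601 genes. limma-voom called 0 genes, and DESeq2 called 2. DESeq2 called 6 genes without control library 95 and 6 without control library 115. Groups did not overlap in 9.48% of genes, where chance gives 10%.

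The gene IDs with the smallest p-values are given as values, since none passed the edgeR threshold. ENSRNOG00000001229 was at 38.9 ± 2.74 CPM (SD, n = 3) with canagliflozin and at 16.7 ± 4.17 CPM (n = 3) with isoproterenol alone, a log2 fold change of 1.22 (SE 0.246). It was 1 of the 2 genes that DESeq2 called, with a DESeq2 adjusted p of 0.0238. The other, ENSRNOG00000019118, had 16, 107 and 361 counts in the canagliflozin libraries and 2, 0 and 2 in the isoproterenol libraries. Both DESeq2 calls were lost when the length trend of each library was used as an offset, in the genes tested by edgeR. For ENSRNOG00000001229 the DESeq2 log2 fold change went from 1.23 (SE 0.258) to 1.10 (SE 0.323) and the adjusted p from 0.0267 to 0.454. For ENSRNOG00000019118 the DESeq2 adjusted p went from 0.0327 to 0.0537 while its unadjusted p, 4.47e-06 before and 3.6e-06 after, did not rise, so that call ended through the adjustment. ENSRNOG00000028137 was at 12.0 ± 2.48 CPM with canagliflozin and 2.69 ± 0.733 CPM with isoproterenol alone, a log2 fold change of 2.16 (SE 0.509). ENSRNOG00000045821 was at 24.2 ± 3.32 CPM with canagliflozin and 67.1 ± 30.6 CPM with isoproterenol alone, a log2 fold change of -1.47 (SE 0.331). ENSRNOG00000007607 was at 38.5 ± 6.71 CPM with canagliflozin and 111 ± 14.0 CPM with isoproterenol alone, a log2 fold change of -1.53 (SE 0.358). In each of these 4 genes with a fold change the 3 libraries of one group lay apart from the 3 of the other. These genes were picked for a small p in this same comparison, so their separation is no added support.

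**Figure D3:**
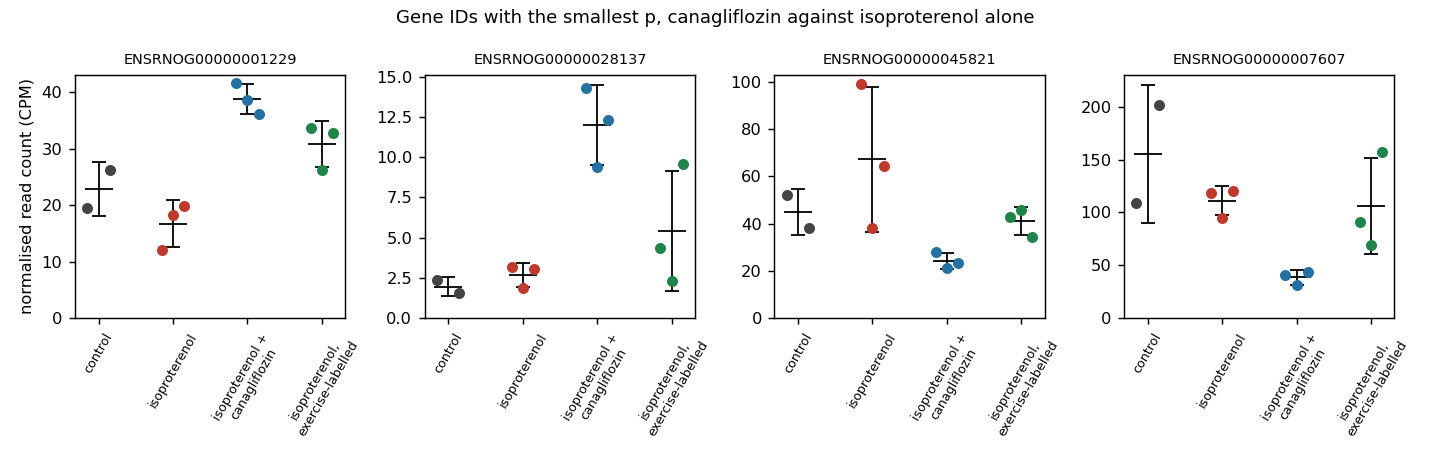
Normalised read counts in CPM, on linear axes, of the 4 gene IDs with the smallest edgeR p-values in each direction for canagliflozin against isoproterenol alone. Each point is 1 library, the short horizontal line is the group mean and the bars are 1 SD (n = 2 in control and 3 in each other group). The canagliflozin libraries of ENSRNOG00000001229 lie between 36.2 and 41.7 CPM and the isoproterenol libraries between 12.0 and 19.9 CPM, and edgeR called none of the 4 genes.

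Exercise-labelled hearts were compared with isoproterenol alone. edgeR called 0 genes, with a smallest adjusted p of 1. There were 222 genes at an unadjusted p under 0.05, 103 higher and 119 lower in the exercise group, where evenly spread p-values give 749. Other splits of the same libraries gave 91 to 732 genes, all below 749, so 222 is not low beside them. limma-voom and DESeq2 each called 0 genes. Groups did not overlap in 8.61% of genes, where chance gives 10%. ENSRNOG00000011533 was at 12.9 ± 3.91 CPM (SD, n = 3) in the exercise group and 4.61 ± 0.295 CPM (n = 3) with isoproterenol alone, a log2 fold change of 1.49 (SE 0.346). ENSRNOG00000061215 was at 71.0 ± 28.9 CPM in the exercise group and 32.4 ± 5.999 CPM with isoproterenol alone. ENSRNOG00000052758 was at 28.05 ± 0.547 CPM in the exercise group and 46.8 ± 5.14 CPM with isoproterenol alone, a log2 fold change of -0.74 (SE 0.203). ENSRNOG00000013092 was at 1.64 ± 0.0514 CPM in the exercise group and 4.73 ± 1.66 CPM with isoproterenol alone.

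The exercise and canagliflozin groups were compared directly, which tests whether their differences from isoproterenol alone differ. edgeR called 0 genes, with a smallest adjusted p of 0.999. There were 363 genes at an unadjusted p under 0.05, 126 higher and 237 lower in the exercise group, where evenly spread p-values give 749. This count was 948 in a fit of only the groups compared, 1232 with a surrogate variable and 81 without canagliflozin library 143. Whether it lies above or below 749 therefore depends on the fit. Other splits of the same libraries gave 65 to 513 genes, all below 749, so 363 is not low beside them. limma-voom called 0 genes and DESeq2 called 1, ENSRNOG00000006889, which had 0 counts in the canagliflozin libraries and 0, 59 and 7 counts in the exercise libraries. Groups did not overlap in 14.5% of genes, where chance gives 10%. ENSRNOG00000007607, among the IDs with the smallest p against isoproterenol alone, was at 106 ± 45.9 CPM (SD, n = 3) in the exercise group, a log2 fold change of 1.46 (SE 0.357) against canagliflozin. ENSRNOG00000049911 was at 29.2 ± 12.8 CPM in the exercise group and 10.9 ± 1.28 CPM (n = 3) with canagliflozin. ENSRNOG00000011752 was at 33.5 ± 4.16 CPM in the exercise group and 62.4 ± 11.4 CPM with canagliflozin, a log2 fold change of -0.90 (SE 0.208). A joint test for any difference among the 3 isoproterenol-treated groups called 0 genes with edgeR, DESeq2 and limma-voom, with 284 genes at an unadjusted edgeR p under 0.05. The 284 became 548 in a fit of only these groups, 919 with a surrogate variable and 121 without canagliflozin library 143. In the joint test DESeq2 called 5 genes without control library 95, and edgeR called 7 without libraries 57, 78, 95 and 98, which were left out because they lay apart within their groups. Both of these fits were chosen after the data had been seen.

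The canagliflozin group was also compared with control. edgeR called 0 genes, with a smallest adjusted p of 0.318. There were 2162 genes at an unadjusted p under 0.05, 857 higher and 1305 lower with canagliflozin, where evenly spread p-values give 749. There were 397 without control library 95. limma-voom called 0 genes. DESeq2 called 178 genes, 57 higher and 121 lower. Groups did not overlap in 26.3% of genes, where chance gives 20%. The DESeq2 count was 2 without control library 95 and 4875 without control library 115, and the edgeR counts were 0 and 3900.

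ENSRNOG00000003869 was at 210.5 ± 6.14 CPM (SD, n = 3) with canagliflozin and 70.2 ± 8.17 CPM (n = 2) in control, a log2 fold change of 1.58 (SE 0.278) with an edgeR adjusted p of 0.318 and a DESeq2 adjusted p of 5.03e-08. It was at 141 ± 23.6 CPM (n = 3) in the exercise group. Its higher control library was at 76.0 CPM, below the lowest of the 9 isoproterenol-treated libraries at 114 CPM. The gene was picked for a small p in this comparison, so this separation is in part fixed by the choice and is no added support. ENSRNOG00000003869 was 1 of the 2 genes that DESeq2 called in this comparison without control library 95, with a DESeq2 adjusted p of 0.00361. ENSRNOG00000043031 was at 12.9 ± 3.26 CPM with canagliflozin and 85.6 ± 50.5 CPM in control, a log2 fold change of -2.73 (SE 0.472). Its control values were 49.9 CPM in library 115 and 121 CPM in library 95, so the size of the change rests in part on library 95. ENSRNOG00000007607 was at 155.6 ± 65.5 CPM in control, a log2 fold change of -2.01 (SE 0.389) for canagliflozin. Its control values were 109 CPM in library 115 and 202 CPM in library 95.

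Exercise-labelled hearts were compared with control in the same way. edgeR called 0 genes, with a smallest adjusted p of 0.852. There were 727 genes at an unadjusted p under 0.05, 202 higher and 525 lower in the exercise group, where evenly spread p-values give 749. limma-voom called 0 genes and DESeq2 called 11, 1 higher and 10 lower. Without control library 95 DESeq2 called 1 gene. Groups did not overlap in 17.4% of genes, where chance gives 20%. ENSRNOG00000012458 was at 3.70 ± 2.29 CPM (SD, n = 3) in the exercise group and at 11.5 and 103 CPM in the control libraries. ENSRNOG00000054508 was at 2.26 ± 0.0627 CPM in the exercise group and at 3.599 and 24.4 CPM in the control libraries. Their log2 fold changes went from -3.94 to -1.61 and from -2.62 to -0.66 without control library 95. edgeR called 2766 genes without control library 115 and 0 without control library 95, where 117 genes had an unadjusted p under 0.05.

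The series asks whether treatment undoes the change made by isoproterenol. The log2 fold changes of isoproterenol against control were correlated, across genes, with those of each treated group against isoproterenol. Genes are not independent replicates, and both fold changes use the isoproterenol libraries, so unchanged groups give a negative correlation. For canagliflozin, Pearson's r was 0.0638, where 50 simulations of unchanged groups gave a mean of -0.422, and the covariance was 0.0360, where they gave -0.217. For exercise, r was -0.305 against a simulated mean of -0.424, and the covariance was -0.142 against -0.219. Neither r was below its simulated mean. The value for canagliflozin changed sign when control library 95 (-0.187) or isoproterenol library 79 (-0.0359), 98 (-0.239) or 119 (-0.106) was left out. For exercise it was -0.0518 without control library 115 and -0.568 without isoproterenol library 98. The covariance exceeded the simulated one by 0.253 for canagliflozin and by 0.0769 for exercise. The simulations drew each gene independently, and their r spanned only -0.459 to -0.395 for canagliflozin. Over random regroupings of the libraries r ran from -0.8834 to 0.125 for canagliflozin and from -0.8835 to 0.219 for exercise. Both observed r lay inside these ranges, which almost any value would. For canagliflozin 99 of 100 regroupings were at or below the observed r, so it lay near the upper end, away from reversal. For exercise 74 of 100 were. An excess over the simulations does not by itself show a departure from unchanged groups. The place of the canagliflozin r does not settle it either, since its sign changed without control library 95. The 3 isoproterenol libraries are too few to be split into sets of at least 2, so neither value was recomputed on separate libraries.

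Fold changes varied with the length of the gene model. Across genes, Spearman's correlation of log2 fold change with length was 0.252 for canagliflozin against isoproterenol, 0.315 for canagliflozin against control and -0.373 for exercise against canagliflozin. For exercise against canagliflozin the median log2 fold change was 0.20 in genes up to 1479 bases and -0.28 in genes from 3852 bases. The trend differed within groups. Spearman's correlation of a library's deviation from the mean of all libraries with length was 0.388, 0.283 and -0.0541 in canagliflozin libraries 143, 133 and 78. In exercise libraries 57, 113 and 103 it was -0.196, -0.0503 and -0.0311. With the length trend of each library as an offset, edgeR, which had called 0 genes without it, called 0 in each comparison. In the genes tested by edgeR, the same offset took the DESeq2 count from 2 to 0 for isoproterenol against control, from 2 to 0 for canagliflozin against isoproterenol, from 1 to 0 for exercise against canagliflozin, from 11 to 1 for exercise against control and from 240 to 152 for canagliflozin against control. For exercise against control the 1 gene, ENSRNOG00000012458, was not among the 11, since its DESeq2 adjusted p was not given without the offset. DESeq2 leaves some genes out of its adjustment. For isoproterenol and for exercise against control, genes left out without the offset were adjusted with it. Part of the fall in these counts may therefore come from a different adjustment. Among all 32883 IDs, DESeq2 gave no adjusted p to 29677 for isoproterenol against control and to 30849 for exercise against control. These include the 12047 IDs at 0 in every library. A lost call does not show that length made the difference: the DESeq2 log2 fold change of ENSRNOG00000019118 for canagliflozin against isoproterenol was 6.75 (SE 1.47) before and 6.63 (SE 1.43) after, and that of ENSRNOG00000003869 for isoproterenol against control also moved by less than its SE. Other lost genes moved more. ENSRNOG00000006889, for exercise against canagliflozin, went from 20.8 to 6.68 (SE 4.085 in both), with 0 counts in the canagliflozin libraries. ENSRNOG00000013589, for isoproterenol against control, went from 0.91 (SE 0.210) to 0.65 (SE 0.283). For exercise against control, the lost genes of 171 to 483 bases all shrank, each by less than its SE. ENSRNOG00000032807, at 245 bases, went from -3.72 (SE 0.9978) to -2.79 (SE 0.8085). The lost lower gene of 3167 bases, ENSRNOG00000028505, grew from -3.13 (SE 0.834) to -3.57 (SE 0.8714). These shifts followed length, but the offset was built from the length trend of these same libraries. ENSRNOG00000003869 was still called by DESeq2 for canagliflozin against control with the offset, at an adjusted p of 8.26e-09.

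Libraries deviated from their group means along a shared axis. The first component of these deviations held 58.3% of the variance within groups. The control libraries lay at 117 and -117 on it and the others between -39.9 and 64.4, so the control pair weighs heavily on this share. In the 9 isoproterenol-treated libraries alone, the first component held 47.0%. Control library 95, isoproterenol library 98, canagliflozin library 78 and exercise library 57 lay on one side of the component from all 11 libraries.

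**Figure D4:**
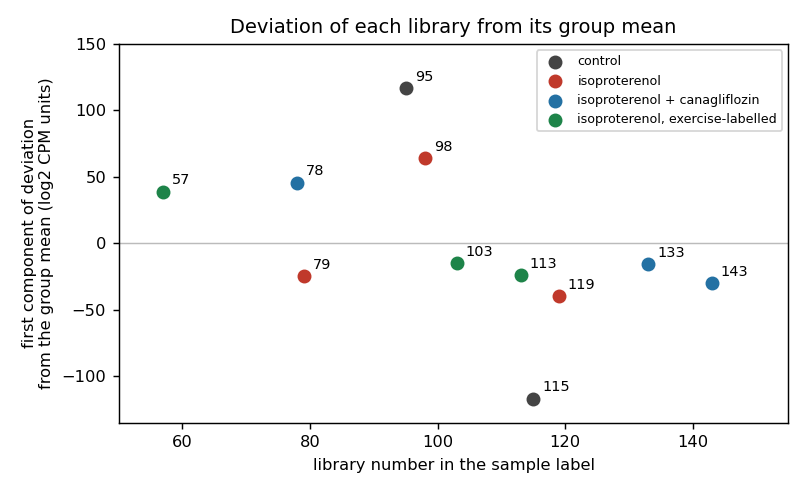
First principal component of each library's deviation from its group mean, in log2 CPM units, against the library number in the sample label. Each point is 1 library, coloured by group. Libraries 95, 98, 78 and 57 lie above 0 and the others below, and the 2 control libraries mirror each other because a group of 2 deviates equally from its mean.

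The spread between libraries set what could be detected. The common biological coefficient of variation was 0.462, estimated over all 11 libraries. The SD of deviations from the group mean was 0.969 in each control library and 0.340 to 0.753 in the others. The values below therefore carry the spread of the control libraries, also for comparisons that do not use them. The median 95% half-width of a log2 fold change was 0.99 for canagliflozin against isoproterenol, a 1.98-fold change, and 1.11 for isoproterenol against control, a 2.16-fold change. In counts simulated with the fitted spread, edgeR called 0.299% of genes changed 2-fold, 18.8% of those changed 4-fold and 53.3% of those changed 8-fold for isoproterenol against control. For canagliflozin against isoproterenol it called 1.49%, 35.8% and 70.0%. Differences of 2-fold or less in single genes were therefore mostly not detectable here, and a count of 0 does not show that genes were unchanged.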

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

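Alternatives with sample quality weights, with library number below 100 as a covariate, without libraries 57, 78, 95 and 98, with DESeq2 without control library 95 and without the 10 most abundant genes were chosen after the data had been seen. edgeR called 0 genes in all 7 tests under each other normalisation, each filter, thinning, a surrogate variable, the number covariate, fits of only the groups compared, no robust estimation and removal of the 10 most abundant genes, and in the 6 comparisons of 2 groups with a 2-fold threshold; limma-voom without weights also called 0. DESeq2 called 2 genes for isoproterenol against control, 2 for canagliflozin against isoproterenol, 1 for exercise against canagliflozin, 178 for canagliflozin against control and 11 for exercise against control. With the length trend as an offset, in the genes tested by edgeR, these were 0, 0, 0, 152 and 1, against 2, 2, 1, 240 and 11 without it. For isoproterenol and for exercise against control the offset also changed which genes DESeq2 adjusted. Without control library 95, DESeq2 called 1, 6, 1, 2 and 1 in that order and 5 in the joint test. An unadjusted p under 0.05 with a 1.5-fold change, which makes no correction for the number of genes, gave 770 genes for isoproterenol against control, 455 for canagliflozin against isoproterenol, 196 for exercise against isoproterenol, 308 for exercise against canagliflozin, 2128 for canagliflozin against control and 723 for exercise against control. Quality weights gave 2 genes for canagliflozin against isoproterenol and 3 for exercise against canagliflozin, with ENSRNOG00000007607 in both at adjusted p of 0.0455 and 0.0476 (limma-voom); the cause was not tested. Without libraries 57, 78, 95 and 98, edgeR called 3 for canagliflozin against isoproterenol, 2 for exercise against isoproterenol, 1 for exercise against canagliflozin, 2 for canagliflozin against control and 7 in the joint test, but these libraries lay apart within their groups, and removing them by itself lowers the spread.

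Leaving out 1 library at a time gave 0 to 2688 genes for isoproterenol against control, 0 to 3900 for canagliflozin against control and 0 to 2766 for exercise against control, with each highest value without control library 115, which leaves library 95 as the only control. It gave 0 genes in the other 3 comparisons and the joint test. The correlation that asks about reversal ranged from -0.239 to 0.152 for canagliflozin and from -0.568 to -0.0518 for exercise. For canagliflozin it was reversed without control library 95 (-0.187) and without isoproterenol libraries 79 (-0.0359), 98 (-0.239) and 119 (-0.106); the cause was not tested. Of the log2 fold changes of the IDs chosen by the rule, none of which edgeR called with all libraries, 0 reversed and 10 passed the threshold, each without control library 115. Some sizes rested on control library 95: without it ENSRNOG00000003136 went from -4.71 to -0.24 and ENSRNOG00000033130 from -6.25 to -1.14 (isoproterenol against control).

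No paired analysis was possible because the groups share no library number. Tests of gene lists, removal of mitochondrial and hemoglobin genes and a reversal test over called genes were not run, because no ID was matched to a symbol and edgeR called no gene for isoproterenol against control. Depth limits genes near the floor, such as ENSRNOG00000033202.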

Other observations

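The tests of library number and of control group membership, and the choice of counts at an unadjusted p for other splits of the libraries, were made only after the results had been seen.

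Control library 95 lay farthest from the other libraries, at a mean distance of 1.95 in log2 CPM. Thinning every library to the smallest total left it at 1.87, above the highest of the other 10 at 1.15, which argues against depth. Removing each library's trend with gene model length left it at 1.86 against 1.16, which argues against length as the whole of it. Control library 115 lay 0.767 from the 9 isoproterenol-treated libraries, below the highest of these at 1.12, so it did not stand apart as library 95 did. With no further control library this cannot tell which of these controls is atypical. Membership of the control group is therefore not excluded. RNA quality, tissue makeup or a wrong label may remain, and none of them was tested.

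A library in each group (95, 98, 78 and 57) deviated along a shared axis, with a mean pairwise correlation of deviations of 0.419 (0.324 to 0.522). The 4 were picked for lying on one side of it, where each group has a library by construction. Removing the trend with gene model length left 0.408 and removing the trend with mean expression left 0.4165, and these trends held at most 6.86% and 4.01% of the variance of any of the 4, which argues against length and against a loss of low-abundance transcripts that follows mean expression. The axis correlated with library number over 11 libraries, with r = -0.527 (exact two-sided permutation p = 0.0278 over 432 permutations within groups) and rho = -0.555 (exact permutation p = 0.0394), and r was -0.486 without the 2 farthest numbers. Over the 9 isoproterenol-treated libraries r was -0.648 (exact permutation p = 0.0694), and isoproterenol library 79 went against the trend. A candidate explanation is an order of animals or handling behind the numbers, whose meaning the labels do not give, and no biological explanation was tested.

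DESeq2 called 178 genes for canagliflozin against control where edgeR called 0. Without control library 95 it called 2, and without control library 115 it called 4875, so the calls may stem largely from library 95. Among the genes tested by edgeR, DESeq2 called 240, and 152 with each library's length trend as an offset, so length may account for a part and not the whole. A change made by isoproterenol with canagliflozin remains open and cannot be separated from library 95 with 2 controls.

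Other splits of the same libraries were counted by genes at an unadjusted p under 0.05. For canagliflozin against isoproterenol the real split gave 495 genes and the highest of the others 1601, and 5 of the 10 splits gave at least as many as the real one, itself included. The split with 1601 parted libraries 78, 79 and 98 from 119, 133 and 143, which is also a split of numbers below and above 100, but it was picked out after the counts had been seen and was not tested against the highest count that chance gives. With library number below 100 as a covariate edgeR called 0 genes in this comparison, and the real split gave 539 at an unadjusted p under 0.05. For exercise against isoproterenol the real split gave 222 genes and the highest other 732 (4 of 10 at least as many), and for exercise against canagliflozin 363 and 513 (4 of 10). In these 3 comparisons 10 splits are too few for a share under 0.05. For the joint test of 3 groups, 47 of 100 splits gave at least the real 284 genes, with a highest of 1596, so chance is not excluded.

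Among 100 random regroupings of the 11 libraries, the correlation that asks about reversal was at or below the observed 0.0638 for canagliflozin in 99 and at or below the observed -0.305 for exercise in 74. The regrouped mean was -0.455 (SD 0.219) for canagliflozin.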
